A study of Mus musculus with 19 samples.

How the data were processed

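The study measured polyadenylated transcripts of cultured microglia, the resident macrophages of the brain, from the cortex of C57BL/6 mice aged 10 to 11 months. The animals were either wild type (WT) or carried a human amyloid precursor protein transgene with familial Alzheimer mutations (APP, the J20 line). The cells spent 4 weeks in culture with 10% serum and 5 ng/mL of macrophage colony-stimulating factor. They then received vehicle or 100 ng/mL of lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4) for 6 h and recovered for 16 h in fresh medium. Per the labels' protocols, RNA with an integrity number above 8.5 entered a QuantSeq 3′ library, in which each read starts near the 3′ end of a transcript, and 100-base single-end reads were taken on a NovaSeq instrument. The protocol adds molecular identifiers and ERCC spike-in RNAs. Whether reads with the same identifier were collapsed before counting, and the genome or transcriptome build, the annotation and the tool versions are not given in the sources used here.

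Per the submitters' processing notes, reads went through FastQC, Trimmomatic and kallisto, and DESeq2 is named as well. The deposited values are estimated counts per gene symbol that kallisto gave the authors, already whole numbers in the tables, with 16941 genes in each of the 19 libraries. The smallest total of a gene over the libraries was 10, so genes below that level were absent from the tables used here, and 0 entries were ERCC transcripts. The planned scaling by spike-ins was therefore not run. The estimated counts were rounded to whole numbers before testing, which changed none of them. A library held between 13065257 and 31248988 counts, with a median of 21918747. Because each library is a sample of molecules, a gene absent from a library is reported against a floor of 3 counts in that library, between 0.0963 and 0.249 CPM. These floors cover counting error only. All CPM values were computed here, as counts scaled to a common library total (CPM), with library totals adjusted by the trimmed mean of M values (TMM).

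Groups came from the sample titles: 4 WT vehicle, 5 WT LPS, 5 APP vehicle and 5 APP LPS libraries. The labels do not say which libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical. WT LPS replicate 1 carries library number 5 in its label and 6 in its file. No 2 libraries of a group were copies of each other: the smallest chi-square per degree of freedom between libraries of a group was 85.9 over 36 such pairings. Y-linked transcripts split the libraries into those from males, with more than 100 counts of Ddx3y, and those from females. There were 2 male and 2 female libraries among the WT vehicle libraries, and 2 male and 3 female libraries in each other group.

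The tests were edgeR quasi-likelihood F tests (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in one fit over the 19 libraries with 1 coefficient per group. The filterByExpr rule kept 14113 genes and left out 2828. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were LPS against vehicle within each genotype, APP against WT within each treatment, the genotype by LPS interaction, and APP against WT averaged over both treatments. Gene lists were tested with camera from limma, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the 30 lists that had at least 5 measured genes. Of the 31 lists, the sex-linked one was used only as a check. Beside the call over all genes, list members were counted as adjusted over the list alone.

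The lists cover inflammatory cytokines and chemokines, NF-kB and LPS-response effectors, interferon-stimulated genes, brakes on LPS signalling, alternative-activation genes, homeostatic and disease-associated microglia genes, phagocytic receptors with bridging molecules and engulfment machinery, and complement. They also cover lysosome and phagosome acidification, class I and class II antigen presentation, cholesterol synthesis, lipid efflux with storage and LXR targets, glycolysis, nuclear-encoded oxidative phosphorylation, oxidative stress with metallothioneins, cell division and Alzheimer risk genes of myeloid cells. RNA quality and stress are covered by heat shock, immediate early and mitochondrially encoded transcripts. The remaining lists hold markers of border-associated macrophages, monocytes and neutrophils, lymphocytes, astrocytes, the oligodendrocyte lineage, neurons, endothelium, and pericytes with smooth muscle and fibroblasts. A gene can stand in several lists.

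Named genes follow a rule: of the genes called in a contrast with a mean of at least 10 CPM in the higher group, up to 8 that rose and 8 that fell with the largest changes; where none was called, the 5 with the smallest p; up to 4 members of each list with the smallest p; and App itself. The tests, the lists, the rule for naming genes and the settings listed next were chosen before the data were examined. These other settings were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0 itself, limma voom with library pair as a random effect, no filter on low counts, a filter of at least 5 CPM in at least 4 libraries, fits on the groups of the contrast alone, a block for replicate numbers, a block for consecutive library numbers, terms for sex and for low (up to 22) against high (41 and above) library numbers, and leaving out each library. A filter at a mean of 20 CPM, fits without the libraries numbered 57 to 60, the average of the LPS effects over both genotypes, exact permutation tests of list levels, a test of scaling by library totals without TMM, and the alternatives of the fits with library pairs were added after seeing the data.

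Whether replicate numbers pair the libraries was read from the correlation of their deviations from the group means, over all genes tested. In APP, vehicle and LPS libraries with the same replicate number correlated between 0.130 and 0.352 in all 5 pairs. Other libraries of different groups had a median correlation of −0.0161 and a highest of 0.313, so the lower of the APP values are not set apart from them. The APP pairs also carry consecutive library numbers, so the numbers were taken to pair the APP libraries. In WT, correlations by replicate number ran from −0.0910 to 0.0659, and the numbers were not taken as pairs. Consecutive WT library numbers gave 4 pairs between 0.0959 and 0.292, of which the lowest missed the limit of 0.1. The 6230 genes with a mean of at least 20 CPM were looked at after the data were seen. Over them the WT pairs lay between 0.289 and 0.635, and those in APP between 0.321 and 0.654. Other libraries of different groups had a median of −0.0400 over these genes and a highest of 0.647, above every WT pair. Because the numbers were taken to pair the APP libraries, the fit with library pairs stands beside the LPS comparison in APP. WT values with pairs are named as such where they are given.

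EdgeR in the group and paired fits, and DESeq2, camera and fry for LPS in APP, were tested on simulated data with known changes, drawn from the means and dispersions of these libraries; limma voom, camera with an estimated correlation and the exact permutation tests were not. In the simulated LPS comparison in WT, the group fit over 14113 genes recovered 4 of 67 genes changed 2-fold, 23 of 67 changed 4-fold and 33 of 66 changed 8-fold, with 4 unchanged genes called. In the simulated LPS comparison in APP, it recovered 4, 30 and 29 of them, with 3 unchanged genes called. For the same APP data DESeq2 recovered 16, 35 and 39, with 74 unchanged genes called. The fit with library pairs recovered 11, 21 and 34 in the simulated APP comparison, with 5 unchanged genes called. In a simulated list comparison in APP, camera called the changed list and 0 of 30 unchanged lists. The simulated genes were drawn independently, so this cannot show how camera or fry behaves where genes of a list vary together.

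Gene locations are from the GENCODE M21 annotation of GRCm38, matched by symbol, which held 15776 of the 16941 symbols. It may not be the annotation of the deposited values, and the locations entered no test. Genes that share 3′ sequence with near copies can exchange counts in kallisto, so members of such families are less certain. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.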

Results

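The dataset holds 19 libraries of cultured adult cortical microglia in 4 groups, formed by genotype (WT or APP) and treatment (vehicle or LPS). Library totals were 17712123 to 31248988 counts in WT vehicle (n = 4), 15270080 to 25610461 in WT LPS (n = 5), 18990298 to 25502823 in APP vehicle (n = 5) and 13065257 to 23165305 in APP LPS (n = 5). Between 11161 and 14333 of the 16941 genes had at least 1 count in a library. Lrrc17, the most abundant transcript, took 2.33% to 7.18% of a library's counts. The common dispersion of the group fit was 1.05, and 5143 genes had 3 or fewer counts in some library and 100 or more in another. All CPM values below are means ± SD of the libraries of a group, and all adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test unless camera or fry is named.

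The mouse App gene was looked at first. App (GRCm38 chromosome 16, 84949685 to 85173766, minus strand) stood at 1688 ± 395 CPM in WT vehicle (n = 4), 1636 ± 243 in WT LPS, 1649 ± 315 in APP vehicle and 1532 ± 382 in APP LPS (n = 5 each). Single libraries ranged from 982 CPM in APP LPS replicate 3 to 2217 CPM in WT vehicle replicate 2. The difference between genotypes averaged over treatments was −0.06 ± 0.15 (log2, SE) with an adjusted p of 1. Whether reads of the human transgene could count toward App was not examined, so this value does not check the genotype labels.

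Macrophage transcripts were abundant in every library, but at unequal levels. The 74 measured phagocytic genes summed to between 15572 and 25345 CPM in 15 libraries. They summed to 11279, 10309, 9653 and 8795 CPM in WT vehicle replicate 4, WT LPS replicate 5, APP vehicle replicate 5 and APP LPS replicate 5, which carry the library numbers 57 to 60. C1qc, a chain of the complement recognition protein C1q, was at 243, 139, 181 and 90.0 CPM in these 4 libraries and at 418 to 1195 CPM in the others. One such library stands in each group. The summed level of 21 pericyte, smooth muscle and fibroblast markers ranged from 1415 CPM in APP LPS replicate 3 to 6234 CPM in APP LPS replicate 5.

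The first comparison asks how WT microglia that had recovered for 16 h differed from vehicle-treated cells after LPS. LPS-treated WT microglia held higher levels of inflammatory transcripts as a group. Il1b, encoding the cytokine interleukin-1β, was at 39.3 ± 31.4 CPM with vehicle (n = 4) and 312 ± 96.6 CPM with LPS (n = 5), a log2 change of 2.99 ± 0.70 (SE). Tnf, encoding tumour necrosis factor, was at 25.3 ± 7.56 and 78.7 ± 16.2 CPM (1.64 ± 0.35). Apoe, the main apolipoprotein of the brain, was at 525 ± 143 CPM with vehicle and 260 ± 84.8 CPM with LPS, a log2 change of −1.01 ± 0.26. For none of the 3 genes did the ranges of the groups overlap, yet each had an adjusted p of 1 over all genes.

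As a list, inflammatory cytokines and chemokines rose in WT: 27 of 30 measured members had log2 changes above 0, with a median of 0.97 (camera adjusted p = 2.23e-12; adjusted p = 0.0425 with an estimated correlation). Adjusted over the list alone, 2 members passed, and over all genes 0 did. NF-kB and LPS-response effectors rose (36 of 38 above 0, median 0.90, camera adjusted p = 3.34e-16; adjusted p = 0.0425 with an estimated correlation), again with 2 members past the threshold adjusted over the list alone. In this group, Acod1, whose product makes the antimicrobial metabolite itaconate, stood at 82.2 ± 67.1 CPM with vehicle and 353 ± 71.2 CPM with LPS, and Sod2, the mitochondrial superoxide dismutase, at 1134 ± 532 and 2619 ± 545 CPM. Brakes on LPS signalling rose too (18 of 21 above 0, median 0.92, camera adjusted p = 2.79e-08; adjusted p = 0.0258 with an estimated correlation), and 1 member passed adjusted over the list alone. Irak3, an inhibitor of Toll-like receptor signalling, was at 54.1 ± 15.9 and 132 ± 53.2 CPM, and Socs3, a feedback inhibitor of cytokine receptors, at 35.4 ± 21.3 and 79.7 ± 16.1 CPM. Fry gave an adjusted p of 0.0539 for each of these 3 lists. Camera called 7 lists in WT, and 49 of 100 splits of the WT libraries, the real one included, gave as many.

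Interferon-stimulated genes rose by camera (43 of 45 above 0, median 0.74, adjusted p = 1.69e-11), but the adjusted p was 0.291 with an estimated correlation. Irf7, a transcription factor of the interferon response, was at 15.9 ± 12.3 and 46.1 ± 19.7 CPM. Class I antigen presentation (19 of 24 above 0, median 0.28, camera adjusted p = 0.00475) and glycolysis (15 of 20 above 0, median 0.29, camera adjusted p = 0.00384) also rose, both with an adjusted p of 0.291 with an estimated correlation. H2-T22, a class I molecule, had a log2 change of 0.65 ± 0.31, and Pfkl, a phosphofructokinase, 1.19 ± 0.42. Endothelial markers fell (4 of 17 above 0, median −0.44, camera adjusted p = 0.0179; adjusted p = 0.0566 with an estimated correlation). Flt1, a VEGF receptor, was at 30.7 ± 13.3 and 15.3 ± 9.27 CPM, while Pecam1, which macrophages also carry, was at 542 ± 197 and 425 ± 138 CPM. In these 4 lists, 0 members passed adjusted over the list alone.

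Lists of the resting and disease states of microglia were not called in WT in the group fit. Homeostatic genes had a median of −0.14 over 41 members (camera adjusted p = 0.299), disease-associated microglia genes −0.19 over 51 (0.200, with 1 member lower adjusted over the list alone), phagocytic genes −0.07 over 74 (0.446), lysosomal genes −0.06 over 70 (0.312), complement −0.06 over 30 (0.656), and lipid efflux, storage and LXR targets −0.26 over 33 (0.299). Cholesterol synthesis (median −0.07) and alternative activation (−0.04) each had a camera adjusted p of 0.299, and class II presentation (median 0.06) one of 0.623. Oxidative phosphorylation (median −0.04, camera adjusted p = 0.200), oxidative stress (0.16, 0.154) and cell division (−0.01, 0.387) were not called either. With consecutive library numbers as pairs, 1 of which missed the limit for pairing, camera called 15 lists in WT, 6 upward and 9 downward, and 0 with an estimated correlation. Among those downward were disease-associated microglia genes (adjusted p = 4.99e-04; adjusted p = 0.0755 with an estimated correlation), lysosomal genes (adjusted p = 9.64e-04; adjusted p = 0.0755 with an estimated correlation) and phagocytic genes (adjusted p = 0.0449; adjusted p = 0.133 with an estimated correlation).

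Over single genes, edgeR called 0 of 14113 in WT in the group fit, while 516 had an unadjusted p under 0.05, and with consecutive library numbers as pairs it called 21 (17 higher, 4 lower), with 1 left without the pair 9 and 10 and 42 called without the APP pair 59 and 60, which shares the dispersion. In the group fit the 5 genes with the smallest p were Tnf, Il1b, Pomgnt2, Apoe and Pafah2, and none passed. Pomgnt2 was at 0 counts in all 4 vehicle libraries and at 4.96 ± 2.61 CPM with LPS, and Pafah2 at 8.17 ± 2.52 and 23.5 ± 5.72 CPM. DESeq2 on the same counts called 89 genes (64 higher, 25 lower), with a median mean level of 1.12 CPM, and limma voom with library pair as a random effect called 3 that rose, Il1b (log2 3.57, adjusted p = 0.00762), Acod1 and Il1a (log2 2.63 and 3.17, both with an adjusted p of 0.0286), named after their values were seen.

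The same question was asked of APP microglia, where vehicle and LPS libraries form 5 pairs. In APP cells inflammatory transcripts rose as a list, while none of the 4 genes given next passed the test by itself in the group fit. Il1b was at 46.2 ± 50.7 CPM with vehicle and 399 ± 200 CPM with LPS (log2 3.11 ± 0.64, n = 5 each), and Ccl3, a chemokine for monocytes, at 221 ± 79.8 and 637 ± 291 CPM (1.53 ± 0.33). Apoe was at 375 ± 77.2 and 184 ± 31.1 CPM (−1.02 ± 0.25). Trem2, a lipid-sensing receptor whose variants alter Alzheimer risk, was at 139 ± 75.6 and 47.0 ± 28.3 CPM (−1.56 ± 0.56). In the group fit these 4 genes had adjusted p-values of 0.495, 0.495, 0.706 and 0.956.

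**Figure D1:**
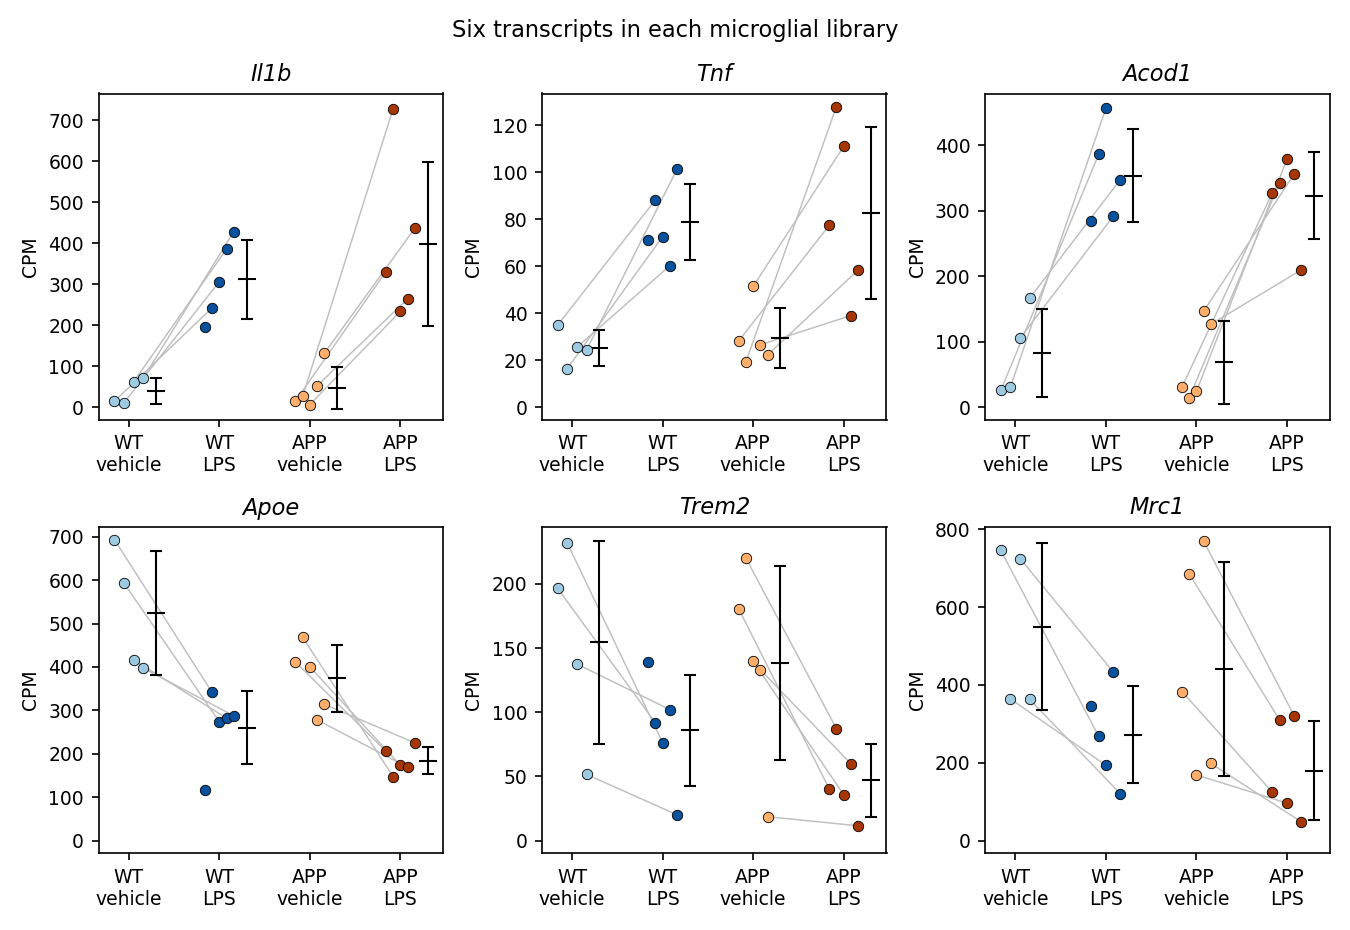
Level in CPM (vertical axes, linear) of Il1b, Tnf, Acod1, Apoe, Trem2 and Mrc1 in each of the 19 libraries, by group; each point is 1 library, the bars are the group mean ± SD, and grey lines join vehicle and LPS libraries with consecutive library numbers. Il1b was at 39.3 and 46.2 CPM on average in the WT and APP vehicle groups and at 312 and 399 CPM in the LPS groups, while each joined LPS library lies below its vehicle partner for Apoe, Trem2 and Mrc1.

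By group, the cytokine list rose in APP (26 of 30 above 0, median 1.15, camera adjusted p = 5.01e-18; adjusted p = 0.0274 with an estimated correlation), and 4 members passed adjusted over the list alone, against 0 over all genes. NF-kB and LPS-response effectors rose (34 of 38 above 0, median 0.85, camera adjusted p = 1.37e-17; adjusted p = 0.0424 with an estimated correlation), with 4 members past the threshold adjusted over the list alone. Fry also gave both lists a shift upward, with adjusted p-values of 0.0411 and 0.0454. Acod1 was at 68.3 ± 63.0 and 323 ± 66.0 CPM, and Nfkbiz, a nuclear regulator of secondary response genes, at 64.9 ± 24.5 and 137 ± 56.5 CPM. Brakes on LPS signalling rose by camera (17 of 21 above 0, median 0.60, adjusted p = 3.86e-05), with an adjusted p of 0.0589 with an estimated correlation and 2 members past the threshold adjusted over the list alone. Socs3 was at 34.6 ± 18.6 and 83.6 ± 31.3 CPM.

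Interferon-stimulated genes rose by camera (41 of 45 above 0, median 0.52, adjusted p = 7.60e-18), as did class I presentation (20 of 24 above 0, median 0.25, adjusted p = 1.23e-04), both with an adjusted p of 0.166 with an estimated correlation. Igtp, an interferon-inducible GTPase, had a log2 change of 1.14 ± 0.42 (adjusted p = 0.956). The oxidative stress list rose (16 of 29 above 0, median 0.15, camera adjusted p = 0.0190; adjusted p = 0.209 with an estimated correlation), with 2 members past the threshold adjusted over the list alone. Gsr, glutathione reductase, was at 79.3 ± 20.9 and 137 ± 21.7 CPM, and Txn1, thioredoxin, at 864 ± 192 and 1333 ± 134 CPM. Homeostatic microglia genes fell by camera (9 of 41 above 0, median −0.26, adjusted p = 0.0126; adjusted p = 0.582 with an estimated correlation), and 1 member passed adjusted over the list alone. Lipid efflux, storage and LXR targets had a median of −0.37 over 33 genes, with a camera adjusted p of 0.0696, a fry adjusted p of 0.0414 and 2 members past the threshold adjusted over the list alone.

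Camera called 7 lists in APP, and 55 of 100 splits of the APP libraries, the real one included, gave as many. The remaining lists were not called by camera in APP. The medians and adjusted p-values were −0.28 and 0.0727 for disease-associated microglia genes, −0.24 and 0.481 for Alzheimer risk genes, −0.17 and 0.126 for lysosomal genes, −0.09 and 0.475 for phagocytic genes, and −0.10 and 0.598 for complement. They were −0.21 and 0.911 for class II presentation, 0.05 and 0.832 for cholesterol synthesis, whose mean and test were below 0, −0.05 and 0.874 for alternative activation, and 0.04 and 0.383 for glycolysis. Endothelial markers had a median of −0.10 (0.364), and pericyte, smooth muscle and fibroblast markers −0.35 (0.234). Cell division had a median of 0.09 and a test that pointed down (0.872), and oxidative phosphorylation a median of −0.01 and a test that pointed up (0.331).

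Lists that track handling stress, RNA quality and other cell types were not called for LPS in either genotype in the group fit, apart from endothelial markers in WT. Heat shock and unfolded protein genes had medians of 0.03 in WT (camera adjusted p = 0.707) and 0.00 in APP (0.383), immediate early genes of 0.16 (0.707) and 0.14 (0.0542), with means below 0 in both, and mitochondrially encoded transcripts of 0.10 (0.735, with a test that pointed down) and −0.05 (0.874). Alzheimer risk genes had a median of −0.02 in WT and a mean of 0.35 (0.707). Border-associated macrophage markers had medians of 0.19 in WT, with a test that pointed down (0.716), and −0.10 in APP (0.874). The medians were 0.40 (0.284) and 0.15 (0.383, with a mean below 0) for monocyte and neutrophil markers, −2.25 (0.0973) and 1.39 (0.406) for 5 lymphocyte markers near the floor of detection, and −0.16 (0.426) and −0.86 (0.191) for astrocyte markers. They were −0.10 (0.716, with a mean and test above 0) and −0.12 (0.874) for the oligodendrocyte lineage, −0.26 (0.589) and −0.32 (0.874) for neuron markers, whose means and tests lay above 0, and −0.12 (0.362) for pericyte, smooth muscle and fibroblast markers in WT.

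Single genes called in APP varied with the model. In the group fit edgeR called 0 of 14113 genes, with 679 at an unadjusted p under 0.05; the 5 with the smallest p were Il1b, Ccl3, Mecr, Tnf and Dnaaf1, none of which passed. DESeq2 called 76 (22 higher, 54 lower) and limma voom with library pair as a random effect 9 (4 higher, 5 lower). EdgeR without APP vehicle replicate 5 called 1 gene, Il1b (adjusted p = 0.0318), and without APP LPS replicate 5 it called 2, Xylt1 (0.0272) and Entrep3 (0.0488), both lower. Without the libraries numbered 57 to 60 it called 5: Il1b and Ccl2 (both 0.0309) and H2-Q4 (0.0496) were higher, and P2ry12 (0.0303) and Xylt1 (0.0445) lower. In APP LPS replicates 1 to 4, P2ry12 and Entrep3 were at 0 counts and Xylt1 at no more than 1 count; over all 5 replicates they were at 0.516 ± 1.15, 0.534 ± 1.19 and 0.507 ± 1.11 CPM, against 6.94 ± 7.62, 6.86 ± 4.36 and 7.85 ± 3.22 CPM in APP vehicle. Those of these genes outside the naming rule were chosen after their values were seen. With replicate number as a block in both genotypes, 1 gene rose (Il1b, log2 3.74 ± 0.49, adjusted p = 0.00628) and 1 fell (Ugt1a6a). In WT these numbers were not taken as pairs, and the WT libraries share the dispersion of that fit. The planned block of library pairs, in which WT pairs share the dispersion, called 84 genes, of which 42 rose and 42 fell; the 10 APP libraries alone, with the same pairs, gave 33 and 30. Of those, 29 and 25 were also called with all pairs. On the 12308 genes that pass the filter in APP alone, 5 rose (Cxcl1, Il1b, Ptges, S100a8 and Slc7a2) and 8 fell.

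With library pairs, the genes that rose most in APP were Il1a, Il1b, Cxcl2, Cxcl1, Acod1, Il6, Saa3 and Clec4e. Il1b rose by 3.73 ± 0.46 on the log2 scale (adjusted p = 6.45e-04, higher in 5 of 5 pairs), and Cxcl1, a neutrophil chemokine, by 3.13 ± 0.49 (adjusted p = 0.00477, 5 of 5). Il6 rose by 2.30 ± 0.37 (adjusted p = 0.00626) and Saa3, an acute phase protein, by 2.07 ± 0.39 (adjusted p = 0.0147), each in 5 of 5 pairs. Over the cytokine list 9 of 30 genes rose and 0 fell, and 19 rose adjusted over the list alone. Over the NF-kB list 11 of 38 rose, and 23 adjusted over the list alone, among them Slc7a2, an arginine transporter (1.31 ± 0.18, adjusted p = 0.00285), Ptgs2, the inducible cyclooxygenase (0.94 ± 0.14, adjusted p = 0.00417), and Nfkbia, the NF-kB inhibitor (0.93 ± 0.14, adjusted p = 0.00417). Their camera adjusted p-values were 7.44e-19 and 3.19e-19; with an estimated correlation both had an adjusted p of 0.106, and fry gave 0.0205 and 0.0183.

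The genes that fell most with pairs were Cd5l, Rgs2, Slc8a1, Tmem86a, Tmem37, Trem2, Fli1 and Igf1, each lower with LPS in 5 of 5 pairs. With the APP libraries alone and the same pairs, Slc8a1 (adjusted p = 0.0837), Tmem86a (0.0626) and Fli1 (0.0817) did not pass. On the 12308 genes that pass the filter in APP alone, only Rgs2 and Igf1 of these 8 passed, and only Il1b and Cxcl1 of the 8 that rose most. With replicate number as a block in both genotypes, Il1b alone of these 16 passed, and Cd5l, Trem2 and Igf1 had adjusted p-values of 0.285, 0.148 and 0.320. In APP this block holds the same 5 pairs. In WT it joins libraries that were not taken as pairs, and these share the dispersion. Igf1 had a log2 change of −1.41 ± 0.36 in that fit, with a larger SE than with library pairs. With library pairs, Cd5l, a secreted macrophage scavenger protein, fell by 2.35 ± 0.43 on the log2 scale (adjusted p = 0.0131), Trem2 by 1.47 ± 0.21 (adjusted p = 0.00400) while Igf1, a growth factor, fell by 1.41 ± 0.17 (adjusted p = 5.12e-04). Disease-associated microglia genes fell as a list (10 fell and 1 rose of 51, 19 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.00102), although the adjusted p was 0.106 with an estimated correlation. Apoe fell by 1.01 ± 0.15 (adjusted p = 0.00417), Lpl, lipoprotein lipase, by 0.88 ± 0.13 (adjusted p = 0.00417) and Ctsd, a lysosomal protease, by 0.76 ± 0.12 (adjusted p = 0.00421). Homeostatic genes (2 of 41 fell, with 12 that fell and 1 that rose adjusted over the list alone, camera adjusted p = 9.51e-05), lipid genes (5 of 33 fell and 1 rose, with 11 and 3 adjusted over the list alone, camera adjusted p = 0.0120) and lysosomal genes (4 of 70 fell, 13 adjusted over the list alone, camera adjusted p = 0.00769) fell as lists. With an estimated correlation each of these 3 had an adjusted p of 0.106, and fry gave 0.00269, 0.00269 and 9.79e-04.

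Phagocytic receptors and engulfment machinery, the process named in the title of the series, were not called by camera with pairs (median −0.14, adjusted p = 0.148; adjusted p = 0.145 with an estimated correlation). Fry placed their balance downward (adjusted p = 9.79e-04), and 4 of 74 members fell and 1 rose, with 17 and 4 adjusted over the list alone. Mrc1, the mannose receptor, fell by 1.37 ± 0.16 on the log2 scale (adjusted p = 5.12e-04) and C1qc by 0.66 ± 0.12 (adjusted p = 0.0110), each in 5 of 5 pairs. Class I presentation rose by camera with pairs (adjusted p = 9.51e-05; adjusted p = 0.209 with an estimated correlation), with 1 of 24 members called, H2-Q4 (1.15 ± 0.23, adjusted p = 0.0275), which did not pass with the APP libraries alone (adjusted p = 0.0600) or with replicate number as a block in both genotypes (0.296). Pericyte, smooth muscle and fibroblast markers (median −0.48, camera adjusted p = 0.0401) and astrocyte markers (median −0.68, camera adjusted p = 0.0411) fell alongside, with adjusted p-values of 0.322 and 0.145 with an estimated correlation. Leaving out the pair numbered 7 and 8 lowered the 84 calls to 9, the pair 11 and 12 to 25 and the pair 3 and 4 to 40, whereas without the pair 59 and 60 there were 164.

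**Figure D2:**
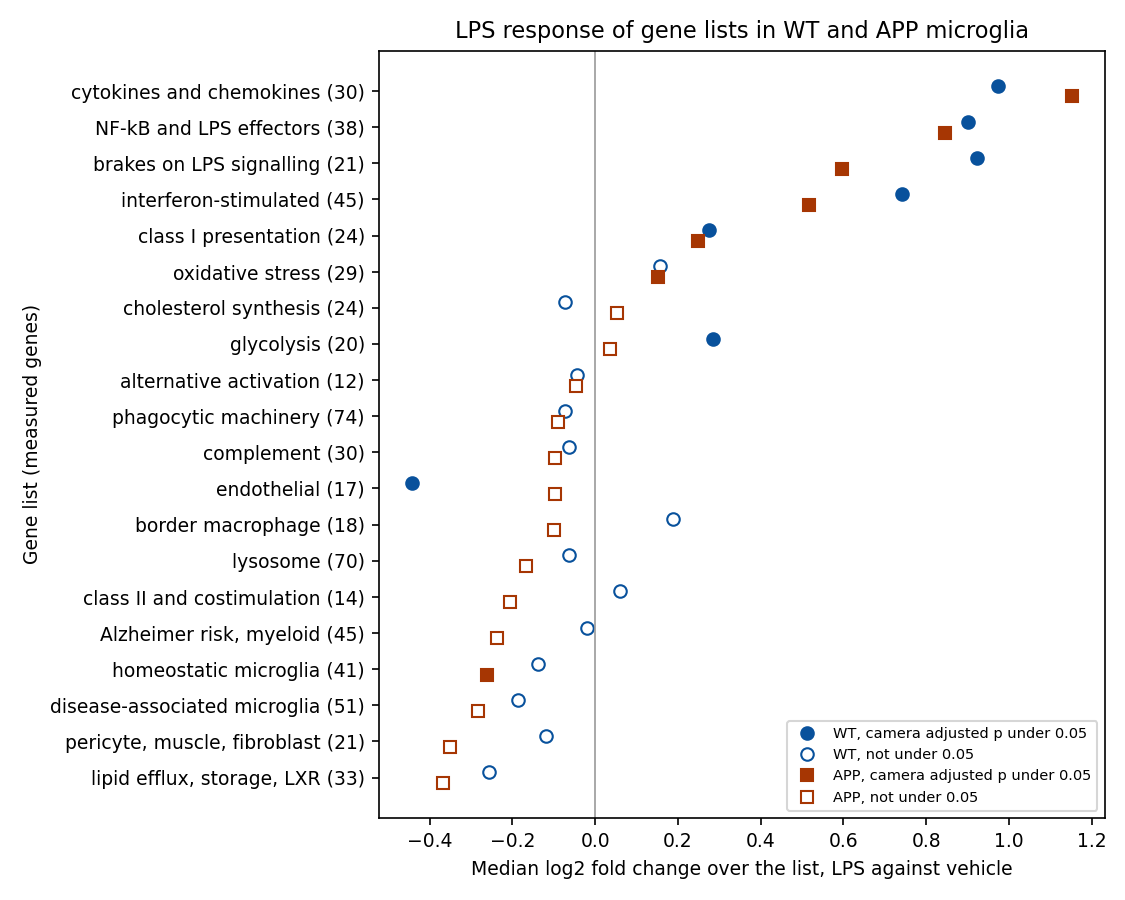
Median log2 fold change of LPS against vehicle over the measured genes of 20 of the 30 tested lists (vertical axis, number of measured genes in brackets) in WT (circles) and APP (squares), from the group fit; filled symbols have a camera adjusted p under 0.05 with the preset correlation. Cytokines stand at 0.97 in WT and 1.15 in APP, and lipid efflux, storage and LXR targets at −0.26 and −0.37.

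Whether the genotypes responded differently to LPS was tested as an interaction. After LPS, Tnf was at 78.7 ± 16.2 CPM in WT and 82.7 ± 36.7 CPM in APP (n = 5 each), and Acod1 at 353 ± 71.2 and 323 ± 66.0 CPM, differences within the spread of the libraries. Ccl3 had an interaction of 0.67 ± 0.47 (log2, SE, adjusted p = 1), with 539 ± 151 CPM in WT LPS and 637 ± 291 in APP LPS. Tm7sf2, a sterol reductase, was at 23.1 ± 11.4 and 8.82 ± 5.94 CPM in WT vehicle and LPS and at 12.1 ± 6.87 and 16.7 ± 9.29 CPM in APP (interaction 1.86 ± 0.84, adjusted p = 1). EdgeR called 0 of 14113 genes, with 385 at an unadjusted p under 0.05, and camera called 0 of 30 lists. DESeq2 called 99 (26 higher, 73 lower) and limma voom 0.

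The genes with the smallest interaction p were Ccdc57, Rai2, Kcnh7, Dnaaf1 and Ace, each with a group of libraries at 0 counts. Ccdc57 was at 0 in WT vehicle and APP LPS and at 2.26 ± 1.92 and 3.47 ± 3.90 CPM in WT LPS and APP vehicle, and Ace at 0, 0, 1.58 ± 2.59 and 1.89 ± 2.03 CPM in the same order. With replicate number as a block, 1 gene was called, Ugt1a6a (adjusted p = 0.0278), a detoxifying enzyme gene whose 3′ exons are shared by the Ugt1a family. In WT these numbers were not taken as pairs. With library pairs, edgeR called 0 genes (279 at an unadjusted p under 0.05, 63 by DESeq2, 0 by voom) and 1 without the pair 57 and 58, mt-Nd4l (adjusted p = 3.28e-07, chosen after its value was seen), also without the pairs 57 and 58 and 59 and 60 (adjusted p = 3.75e-09). Mt-Nd4l was at 0 counts in all APP LPS libraries and, in these fits, in all WT vehicle libraries; over all libraries it was at 28.1 ± 56.3 CPM in WT vehicle, 30.8 ± 42.7 CPM in WT LPS and 108 ± 110 CPM in APP vehicle. Camera then called oxidative phosphorylation (57 of 76 members above 0, median 0.12, adjusted p = 8.01e-04; adjusted p = 0.901 with an estimated correlation) and the 5 measured lymphocyte markers (adjusted p = 0.0102; adjusted p = 0.570 with an estimated correlation), which stood at the floor of detection in most libraries. Without the pairs 57 and 58 and 59 and 60, camera called 0 lists.

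The LPS responses of both genotypes rest on separate libraries and can be compared directly. Across the 14113 genes, the log2 changes in WT and APP correlated with a Pearson r of 0.0748 and had the same sign for 57.7% of genes. Across the 6230 genes with a mean of at least 20 CPM, r was 0.444 and the same sign held for 61.9%. Genes are not independent replicates, so no p is given. No gene was called in either group fit, so there was no overlap of calls to count.

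APP and WT microglia were then compared without LPS. With vehicle, no microglial gene passed the test between the genotypes. Apoe was at 525 ± 143 CPM in WT (n = 4) and 375 ± 77.2 CPM in APP (n = 5), a log2 difference of −0.49 ± 0.26 with an adjusted p of 1, and Ccl6, a chemokine of myeloid cells, at 3123 ± 1070 and 1619 ± 1625 CPM (−0.95 ± 0.53). Itgav, an integrin chain that binds bridging molecules on dying cells, differed by 0.68 ± 0.36 on the log2 scale (adjusted p of 1). EdgeR called 0 of 14113 genes, with 402 at an unadjusted p under 0.05, DESeq2 64 (54 higher in APP, 10 lower) and limma voom 0. The smallest p-values belonged to Flrt3 and Pomgnt2, both at 0 counts in all 4 WT vehicle libraries and at 2.60 ± 2.22 and 2.46 ± 1.65 CPM in APP, and to Slc25a1 (15.7 ± 2.26 and 41.2 ± 20.7 CPM), Pafah2 (8.17 ± 2.52 and 21.0 ± 7.04 CPM) and Tfb2m (40.6 ± 11.3 and 21.9 ± 3.45 CPM), none of which passed.

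No list separated the genotypes with vehicle in the group fit, whose values are given below. Camera called 3 with the replicate block and 2 without the libraries numbered 57 to 60. For contrasts between genotypes this block joins WT and APP libraries by replicate number. Over all genes tested, such libraries correlated between −0.0818 and 0.313, and no pairing of them was shown. The camera adjusted p was 0.200 for disease-associated microglia genes (median −0.06), complement (−0.08), lysosomal genes (−0.06), Alzheimer risk genes (−0.08) and interferon-stimulated genes, whose median of 0.12 and mean lay above 0 while the test pointed down. It was 0.237 for phagocytic genes (median −0.08), 0.564 for cytokines (−0.01, with a mean above 0) and 0.657 for homeostatic genes (−0.07). Markers of pericytes, smooth muscle and fibroblasts had a median of 0.61 and astrocyte markers of 0.76, each with a camera adjusted p of 0.200. APP vehicle replicate 1 held the most astrocyte marker RNA, 901 CPM in sum.

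After LPS, APP microglia were compared with WT microglia in the same way. Pros1, a bridging molecule for the receptors that clear dying cells, was at 122 ± 22.2 CPM in WT and 80.4 ± 35.6 CPM in APP (log2 −0.60 ± 0.30, n = 5 each), and Cd86, a costimulatory molecule, at 28.0 ± 14.4 and 12.1 ± 7.55 CPM (−1.22 ± 0.48). Apoe was at 260 ± 84.8 and 184 ± 31.1 CPM (−0.50 ± 0.24). Postn, an extracellular matrix protein, was at 7.03 ± 2.25 and 26.5 ± 21.1 CPM (1.92 ± 0.62). These 4 genes had adjusted p-values of 1. EdgeR called 0 of 14113 genes, with 482 at an unadjusted p under 0.05; DESeq2 called 69 (20 higher in APP, 49 lower) and limma voom 0. Without the libraries numbered 57 to 60, edgeR called 1 gene lower in APP, P2ry12 (adjusted p = 0.0276), a purinergic receptor of microglia, chosen after its value was seen. It was at 0 counts in all 4 APP LPS libraries of that fit; over all libraries it was at 7.64 ± 5.25 CPM in WT LPS and 0.516 ± 1.15 CPM in APP LPS, with an adjusted p of 1. Mecr, Dnaaf1, Ltc4s, Ppdpf and Fcna had the smallest p: Ppdpf was at 23.2 ± 7.52 CPM in WT and 7.65 ± 3.24 CPM in APP, Mecr and Fcna at 6.80 ± 4.98 and 4.82 ± 0.900 CPM in WT and under the floor of 3 counts in 3 and 4 of the 5 APP libraries, and Dnaaf1 and Ltc4s at 3.36 ± 1.52 and 4.16 ± 5.50 CPM in WT and at 0 in all 5 APP libraries.

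Camera called 0 of 30 lists for genotype in LPS in the group fit. It called 4 with at least 5 CPM in at least 4 libraries and 1 without the libraries numbered 57 to 60. With the replicate block, which again joined WT and APP libraries by replicate number, it called 5. In the group fit its lowest adjusted p was 0.0786, shared by homeostatic genes (10 of 41 above 0, median −0.20, with 1 member lower adjusted over the list alone), disease-associated microglia genes (12 of 51 above 0, median −0.22) and lysosomal genes (10 of 70 above 0, median −0.15), and it was 0.347 for phagocytic genes (25 of 74 above 0, median −0.17). Cytokines had a median of 0.24 (adjusted p = 0.362), and cell division one of 0.37 (40 of 47 above 0, adjusted p = 0.392), where APP LPS replicate 5 held the highest level of any APP LPS library.

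Averaged over both treatments, APP libraries stood slightly below WT libraries for 3 myeloid lists, in a fit that counts the paired vehicle and LPS libraries of APP as independent. Disease-associated microglia genes were lower by camera (12 of 51 above 0, median −0.19, adjusted p = 0.0168), as were lysosomal genes (13 of 70 above 0, median −0.14, adjusted p = 0.0168) and Alzheimer risk genes of myeloid cells (11 of 45 above 0, median −0.20, adjusted p = 0.0187). With an estimated correlation the adjusted p-values were 0.950, 0.960 and 0.950, and fry called 0 lists. Of 100 splits of the samples, the real one included, 86 gave as many lists by camera. Adjusted over these lists alone, 0 members passed. Uqcrq, a subunit of respiratory complex III, was at 563 ± 47.4 and 507 ± 57.0 CPM in WT vehicle and LPS and at 385 ± 78.9 and 364 ± 83.0 CPM in APP (log2 −0.51 ± 0.13, adjusted p = 1). Apoe differed by −0.49 ± 0.18 and Atp6v0d2, a subunit of the proton pump of lysosomes, by −0.79 ± 0.34, both with an adjusted p of 1. EdgeR called 0 of 14113 genes, with 486 at an unadjusted p under 0.05, DESeq2 107 (61 higher in APP, 46 lower) and limma voom 0; Ltc4s, Myoz3, Mecr, Uqcrq and Dnaaf1 had the smallest p. Other phagocytic, complement and homeostatic lists had camera adjusted p-values of 0.0931, 0.0664 and 0.0919, and markers of pericytes, smooth muscle and fibroblasts a median of 0.45 (0.116).

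**Figure D3:**
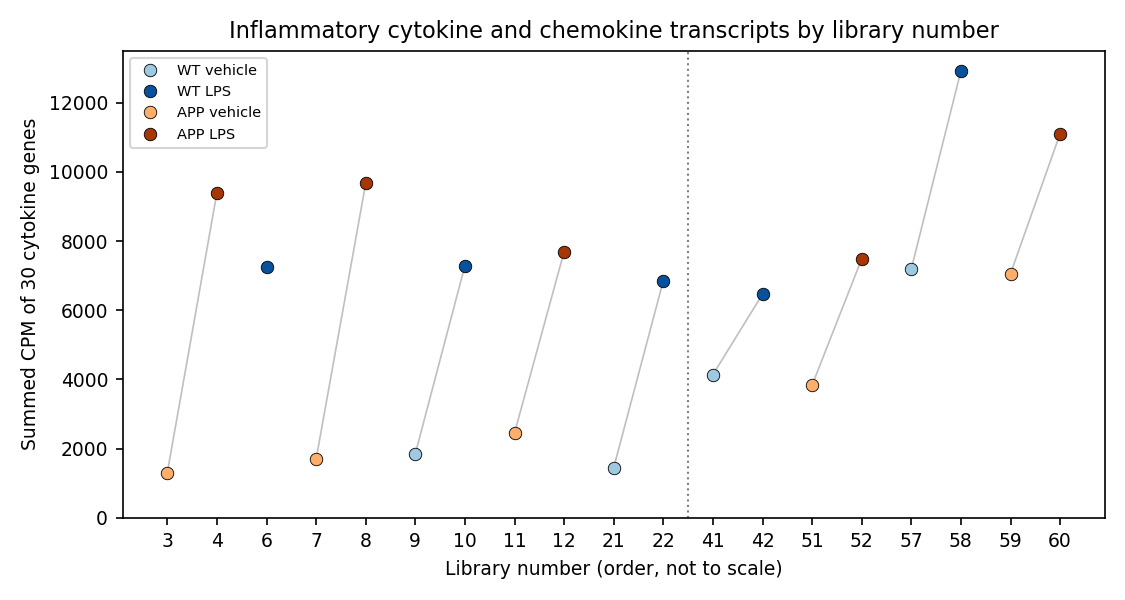
Summed CPM of the 30 measured inflammatory cytokine and chemokine genes (vertical axis, linear) in each library, in order of library number (horizontal axis, not to scale); colours give the group, grey lines join consecutive numbers, and the dotted line parts the numbers up to 22 from those of 41 and above. The 5 vehicle libraries with low numbers lie between 1305 and 2453 CPM and the 4 with high numbers between 3837 and 7196 CPM, and LPS lies above vehicle in 9 of 9 joined pairs.

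Libraries numbered up to 22 and from 41 upward differed in the level of inflammation with vehicle. The 30 cytokine genes summed to 1752 ± 446 CPM in the 5 vehicle libraries with low numbers and to 5558 ± 1818 CPM in the 4 with high numbers (exact permutation test, two-sided p = 0.00794, the smallest this design can give). Among these 4 are the libraries numbered 57 and 59, which were low in macrophage transcripts. Cxcl2 was at 2170 and 1381 CPM in them and at 167 and 361 CPM in those numbered 41 and 51. The lowest of the 4 sums, 3837 CPM, still lay above the highest with low numbers, 2453 CPM. With LPS the sums ran from 6857 to 9669 CPM and from 6468 to 12923 CPM. Low and high numbers both hold vehicle and LPS libraries of each genotype, and LPS lay above vehicle in 9 of 9 pairs of consecutive numbers. With a term for low against high numbers, edgeR called 1 gene for LPS in APP, Il1b (log2 3.73).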

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

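The comparison of libraries within a group was planned, while the tests of cytokine levels by library number were written only after the result was seen. Within each group, a library was singled out where its gap to the nearest other library divided by the group's whole range, was above Dixon's critical value. Genes and list means were taken on the log2 scale. This was done for 460 groups of values, of which 28 stood out, and chance gives about 1 in 20, or 23. The libraries numbered 57 to 60 held 22 of the 28, although they are 4 of 19 libraries.

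Microglial genes were low in these libraries. In WT vehicle replicate 4, the gap took 0.932 of the range for Gpr34, 0.833 for Cx3cr1 and 0.847 for the mean of the homeostatic list. In WT LPS replicate 5 it took 0.716 for Gpr34, 0.764 for C1qc, 0.730 for Tmem86a and 0.809 for the mean of the phagocytic list, all on the low side, and 0.799 for Cxcl2 and 0.831 for Slc7a2 on the high side. In APP vehicle replicate 5 the low values were C1qc (0.722), Ctsa (0.791), Igf1 (0.824), Trem2 (0.796), the disease-associated list (0.840) and the phagocytic list (0.744), with H2-Q4 high (0.736). In APP LPS replicate 5 the low values were Acod1 (0.756), C1qc (0.765), Igf1 (0.783), Lgals3 (0.731) and the phagocytic list (0.762), and the cell division list was high (0.754).

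In other libraries, Apoe (0.795) and the monocyte and neutrophil list (0.791) were low in WT LPS replicate 1, Pfkl was low in APP LPS replicate 1 (0.711), and the astrocyte list was high in APP vehicle replicate 1 (0.781). Outside this rule, APP LPS replicate 1 also had the fewest genes with a count, 11161. On the second principal component of all genes tested it lay at −234, and the other libraries between −29.3 and 53.8. The endothelial list was high in WT LPS replicate 4 (0.785) and low in APP vehicle replicate 3 (0.732). The LPS effect differed between genotypes for Ugt1a6a with replicate number as a block (edgeR adjusted p = 0.0278), although these numbers did not pair the WT libraries. Without a block and with library pairs edgeR called 0 genes, with 385 and 279 at an unadjusted p under 0.05 and 99 and 63 called by DESeq2. With library pairs it differed for oxidative phosphorylation (camera adjusted p = 8.01e-04; adjusted p = 0.901 with an estimated correlation) and lymphocyte markers (camera adjusted p = 0.0102; adjusted p = 0.570 with an estimated correlation).

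Vehicle libraries with numbers of 41 and above held more cytokine transcripts than those with numbers up to 22, as the plot by library number shows. An exchange of vehicle and LPS libraries is argued against, because LPS lay above vehicle in each of the 4 pairs with high numbers, with a smallest log2 ratio of 0.644. More pericytes, smooth muscle cells or fibroblasts in the high-numbered cultures were not seen, but with so few libraries they cannot be excluded. The stromal sums of the vehicle libraries ran from 1434 to 5123 CPM with low numbers and from 1933 to 5560 CPM with high numbers. An exact permutation test of these sums gave a two-sided p of 0.810. The lowest stromal sum of the high numbers minus the highest of the low ones was −3190 CPM, and overlapping ranges alone decide nothing. A different round of culture or library preparation may account for the gap and stays open as well, because the labels give no date or batch. Genotype is spread over both ranges of numbers, and no biological explanation was tested.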

How the results depend on the processing

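The fits without the libraries numbered 57 to 60, the filter at 20 CPM, and all alternatives of the fits with library pairs were chosen only after the results were seen. Where a cause is not named, the cause was not tested. With DESeq2, the 0 calls of edgeR's group fits became 89 for LPS in WT, 76 for LPS in APP, 64 and 69 for genotype in vehicle and in LPS, 99 for the interaction and 107 for the mean over treatments. Limma voom with library pair as a random effect gave 3 and 9 for LPS in WT and APP. As a replicate block, replicate number gave 2 for LPS in APP and 1 for the interaction, and library pairs gave 21 in WT and 84 in APP. Replicate number was not taken to pair the WT libraries, and no pairing by it was shown between genotypes. A term for low or high library numbers gave 1 for LPS in APP. Leaving out 1 library at a time gave 0 to 2 for LPS in APP, and 0 for the other 5 contrasts in edgeR. Without the libraries numbered 57 to 60 there were 5 for LPS in APP (3 higher, 2 lower) and 1 for genotype in LPS.

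For LPS over both genotypes, library pairs gave 214 calls, and leaving out a pair gave 107 to 294. In WT the 21 calls became 1 to 42, in APP the 84 became 9 to 164, and for the interaction there were 0 to 1. For both genotypes the count was 107 without the pair 21 and 22, 119 without 7 and 8 and 121 without 9 and 10. In WT it was 1 without 9 and 10, 5 without 21 and 22, 10 without 57 and 58, 32 without 3 and 4 and 42 without 59 and 60. Without the pairs 57 and 58 and 59 and 60 there were 32 calls in WT, 169 in APP and 1 for the interaction. Without a filter on low counts, there were 335, 67 and 181 for both genotypes, WT and APP. DESeq2 gave 712, 182 and 607, and 63 for the interaction, and limma voom 348, 69 and 127. The APP libraries alone, on their own 12308 genes, gave 13.

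Of the list counts, LPS in WT went from 7 to 3 with an estimated correlation, 0 with fry and 15 with library pairs. LPS in APP went from 7 to 2, 3 and 13, and to 12 with replicate number as a block. Genotype in LPS went from 0 to 4 with at least 5 CPM in at least 4 libraries, 5 with the replicate block and 1 without the libraries numbered 57 to 60. Genotype in vehicle went from 0 to 3 and 2 under the last 2 of these settings, the mean over treatments from 3 to 1 and 9, and the interaction from 0 to 2 and 1. The mean fell to 0 with an estimated correlation and with fry, and the interaction rose to 2 with library pairs. With pairs, an estimated correlation left 0 lists in WT, 0 in APP, 0 for the interaction and 2 for both genotypes. Fry left 5 in WT and 0 for the interaction, which had 1 at a mean of 20 CPM. Without the pairs 57 and 58 and 59 and 60, WT had 8 and the interaction 0.

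The LPS response shared by WT and APP, as a correlation of log2 changes across genes, was 0.0748 over all genes, 0.232 in a fit on genes with at least 5 CPM in at least 4 libraries, 0.446 at a mean of 20 CPM and 0.0974 with DESeq2. Pairing by consecutive numbers rests on a hint from the data. Over both genotypes, 9 of 9 pairs shared their Y-linked status (exact probability 0.0167), and 12 of 18 libraries lay closest to their own partner.

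Values of single genes under alternatives kept their direction and their side of the threshold 3038 times, came past it 69 times, lost it 112 times and changed sign 13 times. All of these 13 were values of App, never called and near 0. For App, LPS against vehicle in WT gave log2 changes between −0.148 (without WT vehicle replicate 3) and 0.114 (without WT vehicle replicate 2), and 0.0157 without WT LPS replicate 2. For App, LPS against vehicle in APP ran from −0.214 (without APP LPS replicate 1) to 0.0177 (without APP LPS replicate 3). For App, APP against WT in vehicle ran from −0.137 (without WT vehicle replicate 3) to 0.126 (without WT vehicle replicate 2), with 0.0530 and 0.00146 without APP vehicle replicates 3 and 4. For App, APP against WT in LPS ran from −0.200 to 0.0293 without APP LPS replicates 1 and 3. For App, APP against WT, mean over both treatments, ran from −0.118 (without APP LPS replicate 1) to 0.0155 (without WT vehicle replicate 2). For App, genotype by LPS interaction values ran from −0.221 (without WT vehicle replicate 2) to 0.0627 (without APP LPS replicate 3). They were 0.0418, 0.00300 and 0.0364 without WT vehicle replicate 3, WT LPS replicate 5 and APP vehicle replicate 5, and 0.0196 without the libraries numbered 57 to 60. Endothelial markers over both genotypes with pairs turned upward at a mean of 20 CPM (adjusted p = 0.999). Scaling by spike-ins was not run. Depth set a floor of 0.0963 to 0.249 CPM in a library.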

Other observations

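The tests of the LPS effect averaged over both genotypes with library pairs, the exact tests of list levels and the test of scaling with library totals were chosen only after the results were seen, and the choice to give WT values with pairs here, in a fit set beforehand, was made although 1 WT pair missed the limit of 0.1. The splits and swaps of samples and the tests of scaling after TMM, macrophage content, shared sequence and captured molecules were written before their outcome. For LPS averaged over both genotypes, the group fit without pairs called 3 genes, of which 2 rose and 1 fell. Over the 9 pairs of consecutive numbers, edgeR called 214 genes for LPS, of which 114 rose and 100 fell. Slc7a2 rose by 1.75 ± 0.14 on the log2 scale (adjusted p = 2.80e-06), Lcn2, an iron-binding protein of innate immunity, by 1.31 ± 0.16 (adjusted p = 1.94e-04) and Ccl2, a monocyte chemokine, by 1.51 ± 0.20 (adjusted p = 3.54e-04), each in 9 of 9 pairs. Slc40a1, the iron exporter ferroportin, fell by 1.41 ± 0.20 (adjusted p = 5.47e-04) and Lipa, lysosomal acid lipase, by 1.00 ± 0.13 (adjusted p = 2.91e-04), each in 9 of 9 pairs. Lysosomal genes (9 of 70 fell, 19 adjusted over the list alone, camera adjusted p = 1.98e-04; adjusted p = 0.0494 with an estimated correlation) and disease-associated microglia genes (12 of 51 fell and 3 rose, 22 and 5 adjusted over the list alone, camera adjusted p = 5.33e-05; adjusted p = 0.0422 with an estimated correlation) fell as lists. Phagocytic genes fell by camera (10 of 74 fell and 4 rose, 20 and 8 adjusted over the list alone, adjusted p = 0.0372; adjusted p = 0.0643 with an estimated correlation).

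In WT alone, pairs gave 17 genes that rose and 4 that fell, the latter being Mrc1, Igf1, Ccdc152 and Ctsb. Leaving out 1 pair moved these 21 calls to between 1 and 42, and without the pair 9 and 10 only Slc7a2 was left. With all pairs, of the genes that rose, 12 were also called in APP, against 0.0506 for independent lists, and of those that fell 3, against 0.0119. WT and APP pairs share no library, but both sets of calls come from the same fit with a shared dispersion per gene. A gene with a low dispersion is likelier to be called in both, so the values for independent lists do not test the overlap. All 42 genes that rose and 42 that fell in APP had the same sign in WT. Among the 90 genes called in either genotype, 14 had an unadjusted interaction p under 0.05, and the smallest adjusted over these genes was 0.0547. Over all 14113 genes, 279 had an unadjusted interaction p under 0.05. The 90 genes were chosen by their LPS effects in the same fit, which favours larger interaction values, so their values do not test a difference between genotypes. Exact permutation tests of mean list levels gave unadjusted two-sided p-values of 0.0159 for cytokines in WT (n = 4 and 5) and 0.0238 in APP, 0.00794 for lipid genes in APP, and 0.0159 for both lipid genes and complement between genotypes in LPS. There were 120 such tests, and their p-values were adjusted over the lists of each comparison separately. Each of the values given here then had an adjusted p of 0.238. These tests exchange libraries freely and ignore the pairs.

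For LPS over both genotypes, chance is argued against by exchanges of vehicle and LPS within pairs. Of 25 exchanges, the real one included, 1 gave 214 genes, with 0 as the highest other, and 1 gave 17 lists, with 11 as the highest other. These 25 were only some of the possible exchanges, and 1 of 25 is the smallest share they can give, just under 0.05. Apart from the real one, each exchanged 2 to 6 pairs, so exchanges of 1 pair were not tried. In WT (21 genes and 1 as the highest other, 15 lists and 12, with 1 of 8 exchanges as large) and in APP (84 genes and 0, 13 lists and 9, with 1 of 16 as large), the exchanges are too few for a share under 0.05. With 0 genes called by edgeR in each contrast of the group fits, 100 of 100 splits had to give as many, so this says nothing about chance. The highest other was 1 for LPS in WT, 3 for LPS in APP, 40 and 1 for genotype in vehicle and LPS, 2 for the interaction and 629 for the mean. The split with 40 calls puts the 5 vehicle libraries with low numbers against the 4 with high numbers. The split with 629 calls points to a structure of the samples, which was not identified; it follows neither the Y-linked counts nor low and high library numbers. For lists chance could not be excluded where some were called: 49 of 100 splits gave the 7 of LPS in WT (highest other 20), 55 the 7 of LPS in APP (17) and 86 the 3 of the mean (19). With 0 lists called for genotype in vehicle, genotype in LPS and the interaction, all 100 had to give as many, and the highest others were 17, 16 and 19. Among the 16 splits that part all 5 APP pairs, 2 gave as many lists, the real one included, and the others had a median of 3 and at most 7. For the 76 DESeq2 calls of LPS in APP, 6 of 25 splits gave as many, and the highest other was 216.

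Most DESeq2 calls of the group contrasts were genes at 3 or fewer counts in some library and at 100 or more in another: 130 of 176 called in any contrast, or 73.9%, against 34.6% of the genes tested. Shared sequence was looked for in the genes with transcripts in GENCODE M21, 118 of these 130 and 13432 of the genes tested. Of the 118, 25.4% shared a 31-base stretch of their last 300 bases with another gene, and of the 13432, 38.3% did. The ratio of 0.663 argues against sequence shared with another gene. Few captured molecules read many times may account for them. The share of calls that were on in a library and off in its pair mate was 0.812 of the share between other libraries, and leaving out a pair moved this from 0.764 to 0.931, so it stays open. For a culture that keeps such genes on or off, a ratio below all of these values was expected beforehand. The calls were chosen for differing between groups, which by itself moves their ratio toward 1. Over all 4885 such genes among those tested, called or not, the ratio was 0.775, and 0.730 to 0.856 leaving out a pair. These values over all such genes argue against a culture that keeps genes on or off as the whole cause, provided that pair mates come from the same culture.

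The genes called lower under LPS in APP with pairs had a median log2 change of −0.99. The median of all genes with a mean of at least 20 CPM, −0.0168, is set near 0 by TMM and decides nothing about scaling. Scaling against the genes that rose is argued against by library totals without TMM, where this median was −0.0446 (−0.0786 to −0.00360 over the 5 pairs) and that of the genes that fell was −1.02. A loss of macrophages as the whole cause is argued against by 24 pan-leukocyte genes, with a median of −0.0850 (quartiles −0.40 and 0.30). Of these genes, 16 lay below 0. EdgeR called 0 of them lower, which says little, since it called only 42 of 14113 genes lower. An effect of LPS on these transcripts within the microglia stays open and was not tested.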
